A study of Mus musculus with 39 samples.

How the data were processed

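Tumors of 20 mice were measured, 5 in each of 4 groups given by the labels: control diet, control diet with DFMO, diet without proline and arginine, and that diet with DFMO. Per the labels, tumors were ground in liquid nitrogen and lysed in the presence of cycloheximide, extracts were digested with RNase I, and monosomes were collected on S-400 columns. Protected fragments were selected by size and depleted of ribosomal RNA, and total RNA for RNA-seq came from the same extracts, so the libraries of a mouse form a pair. Per the submitters' processing notes, reads were processed with cutadapt, Bowtie2 and HISAT2 on GRCm38. The versions of these tools, the counting tool and the annotation release are not given in the sources used here. Each sample is a different mouse, and no label gives batch, sex or age.

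The deposited files hold counts per transcript, which the authors made for 20 footprint and 19 RNA libraries, and the deposited RPKM values of the same libraries. All tests used the counts, and the RPKM values served in a single alternative. Every column was used (0 left over). Of 20333 transcripts, 1 per gene, 20244 were found in GENCODE M21, a reference copy whose release is not necessarily that of the authors, and 1977 had no count in any library. The counted transcript was the longest coding transcript of its gene for 76.9% of genes. Mitochondrially encoded genes had no counts and are not reported. Coordinates are of GENCODE M21 on GRCm38. RNA of control mouse C5840 was not analysed here.

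Counts were tested in R 4.3.3 with edgeR 4.0.16 by the robust quasi-likelihood F test, with TMM scaling, genes chosen by filterByExpr, and all groups in one fit. Efficiency was the interaction of assay and group over all 39 libraries. Adjusted p values are Benjamini-Hochberg over all genes tested, with calls at 0.05. CPM values are counts scaled to the TMM-adjusted library total, and log2 CPM used a prior count of 2. The unadjusted total served for summed CPM of pancreatic and Y-linked genes, for codon scores and for the level allowed to genes without counts. Comparisons were each treatment against control, the combination against each single treatment, and the interaction of diet and DFMO, all set before the data were examined. Gene lists, also fixed before the data were examined, were tested with camera of limma 3.58.1 at its preset correlation of 0.01 and adjusted over the lists. Camera with an estimated correlation and fry were also fixed then, for comparison. Counts adjusted over the list alone use the edgeR p values of the list. Codon scores need a coding sequence of at least 100 codons and were compared by exact permutation of mice, two-sided. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 made the tables and drawings.

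Genes are named by rules fixed before the data were examined. These were 17 genes of polyamine, proline and stress metabolism in the combination against control, the largest changes in each comparison with a mean of at least 10 CPM whose treated libraries all lay beyond all controls (5 each way, or 3 each way for combination against single treatments and the interaction), and up to 4 members with the smallest p of each list that passed. Predicted genes and pseudogenes were left out of the largest changes, and some genes that meet these rules are not reported here.

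Also fixed before the data were examined were refits with RLE scaling, no filter on low counts, DESeq2 1.42.0 (Wald test), limma-trend on log2 RPKM, mice as a block in the 38 libraries of mice with both assays, these 38 libraries without a block, and leaving out each mouse in turn. Chosen after seeing the data were fits without the 4 RNA libraries with under 14000 transcripts detected, without the 3 others whose own footprints were not among the 5 closest, without all 7, and without 4 RNA libraries that looked like mixtures. So were fits without the footprints of mice D5747 and PD5732, with sex as a covariate from Y-linked genes (limit 20 CPM), and with footprints thinned to 2137838 counts each. Both limits that define the low-complexity and unmatched libraries were also set after seeing the values.

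Depth was lowest in control footprints. The tests were tried on simulated data with the depths and spread of these libraries, for the combination against control. Of genes changed 2-fold, 65.7% were recovered in footprints, 4.5% in RNA and 11.9% in efficiency, and of genes changed 4-fold 84.8%, 57.6% and 66.7%. False calls were 7 of 127 in footprints, 1 of 42 in RNA and 1 of 54 in efficiency. Few genes were changed in these simulations, with 67 of 14280 changed 2-fold in RNA, whereas 5827 were called in the real RNA. Adjustment is stricter where few genes change, so recovery in the real data may be higher. The raised list among 20 simulated lists was found, and 0 of the unchanged ones were called. Simulated genes were drawn independently, so this could not show false list calls that come from correlation among genes. The pairing of assays was checked by correlating each mouse's departures from its group mean in RNA and footprints. These correlations ran from -0.35 to 0.625 and were over 0.1 in 10 of 19 mice.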

Results

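TH-MYCN mice develop neuroblastoma from a MYCN transgene expressed in the sympathetic lineage. They received a control diet or a diet lacking proline and arginine, each with or without difluoromethylornithine (DFMO), which blocks ornithine decarboxylase, the entry enzyme of polyamine synthesis. Proline and arginine are both sources of the ornithine that this enzyme uses. Ribosome footprints were sequenced from the tumors of 20 mice, 5 per group, and total RNA from 19 of them. Mice are named by their number after C (control), D (DFMO), P (diet without proline and arginine) or PD (both), and control mouse C5840 had footprints only. Changes are log2 values ± SE. The p values of single genes, of fry and of codon scores measure spread from mouse to mouse. Camera at its preset correlation instead compares the genes of a list with other genes and treats them as nearly independent. Efficiency means footprints relative to RNA.

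Footprint libraries held 2.14 to 12.4 M counts (M, 1e+06) and were shallowest in the controls, at 3.10 ± 0.939 M (SD, n = 5) against 7.85 ± 1.56 M under DFMO, 5.56 ± 2.22 M on the diet and 7.65 ± 2.98 M in the combination. RNA libraries held 10.0 to 51.5 M. RNA of control mice C5696, C5778 and C5781 and of diet mouse P5828 was of low complexity. These 4 libraries detected 8806 to 13387 transcripts against at least 14977 in each other library, and 39.9 to 51.6% of their counts were ribosomal protein mRNA against at most 33.0% elsewhere. Fits without these 4 libraries keep a single control RNA library, C5812, and take their spread from the other groups, so calls can end there from lost power alone. In footprints that share was 12.8% in controls and 12.4% in the combination. Genes moved in RNA against control by a median of 0.28 under DFMO, 0.23 on the diet and 0.31 in the combination, and RLE scaling shifted these medians to 0.41, 0.28 and 0.48. Efficiency moved the opposite way, by -0.18, -0.20 and -0.18. RNA of DFMO mice D135 and D5823 and combination mouse PD5732 was complex but lay far from the footprints of its own mouse. This was measured across genes by correlating departures from the mean of all libraries of the same assay. The RNA of D135 correlated so with its own footprints at r = -0.048, that of D5823 at r = -0.061 and that of PD5732 at r = 0.118.

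**Figure D1:**
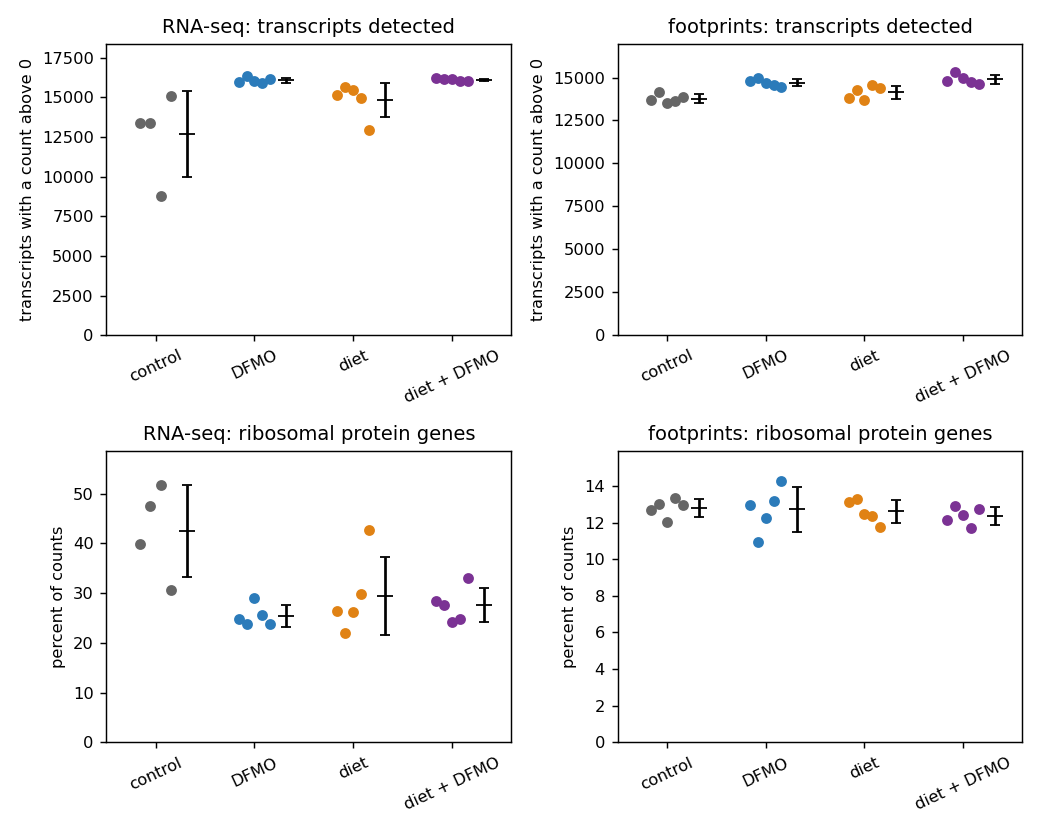
Transcripts detected and percent of counts from ribosomal protein genes in RNA and footprint libraries of the 4 groups. Each point is a mouse, and bars give mean ± SD.

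Under DFMO alone, footprints fell on ribosome biogenesis genes, on chaperones of the endoplasmic reticulum and on the amino acid stress response, and rose on neuronal genes. Of 12095 genes tested in footprints, 1117 rose and 1069 fell. Among 48 MYC targets in ribosome biogenesis, 19 fell and 1 rose (28 and 1 adjusted over the list alone), with a median of -0.29 (camera adjusted p = 1.1e-08, adjusted p = 0.229 with an estimated correlation). Ddx21, a helicase that processes ribosomal RNA (ENSMUST00000045866, chromosome 10, 62580251 to 62602281), fell from 321 ± 27.1 to 179 ± 38.6 CPM (SD, n = 5), a change of -0.84 ± 0.15 (edgeR adjusted p = 0.000889). Nop2, which methylates ribosomal RNA, changed by -0.68 ± 0.12 (edgeR adjusted p = 0.000979). Translation factors followed, with 13 of 46 down and 3 up (18 and 4 adjusted over the list alone, camera adjusted p = 0.00151, adjusted p = 0.525 with an estimated correlation). Eif3b, a core initiation factor subunit, changed by -0.54 ± 0.09 (edgeR adjusted p = 0.000669). The test fry, which asks whether the genes of a list move one way on balance, gave an adjusted p = 0.0031 for the MYC targets. Values of fry are printed here and below only for lists where it passed. Across all comparisons it lost 44 of 80 list calls of camera in footprints, 27 of 54 in RNA and 31 of 45 in efficiency.

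The unfolded protein response lost footprints on 9 of 22 genes under DFMO, with none up (10 down and 1 up adjusted over the list alone, camera adjusted p = 4.67e-05, adjusted p = 0.229 with an estimated correlation). Hspa5, the main chaperone of the endoplasmic reticulum, changed by -0.47 ± 0.09 (edgeR adjusted p = 0.00204), its partner Hyou1 by -0.67 ± 0.10 (edgeR adjusted p = 0.00021) and the secreted survival factor Manf by -0.79 ± 0.13 (edgeR adjusted p = 0.0004). Of 36 ATF4 targets, 12 fell and 1 rose (15 and 1 adjusted over the list alone, camera adjusted p = 2.66e-05, adjusted p = 0.229 with an estimated correlation). Among them the alanyl-tRNA synthetase Aars changed by -0.42 ± 0.08 (edgeR adjusted p = 0.00196) and the mTORC1 inhibitor Ddit4 by -0.82 ± 0.18 (edgeR adjusted p = 0.00361). Proline and arginine metabolism had 4 genes down and 2 up of 26 (5 and 2 adjusted over the list alone, camera adjusted p = 0.0164, adjusted p = 0.229 with an estimated correlation). Aldh18a1, which makes the proline precursor (ENSMUST00000025979, chromosome 19, 40550257 to 40588463), changed by -0.54 ± 0.14 (edgeR adjusted p = 0.00969) and the arginine transporter Slc7a1 by -0.49 ± 0.10 (edgeR adjusted p = 0.00212).

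Neuronal genes rose in footprints under DFMO, 13 of 50 with 1 down (14 and 1 adjusted over the list alone, camera adjusted p = 0.000293, adjusted p = 0.495 with an estimated correlation). Gfra2, a receptor for neurturin (ENSMUST00000022699, chromosome 14, 70890120 to 70979838), rose from 4.15 ± 0.746 to 22.2 ± 13.3 CPM (SD, n = 5; log2 2.46 ± 0.34, edgeR adjusted p = 0.00021). The neuronal RNA-binding protein Elavl4 (ENSMUST00000106600, chromosome 4, 110203722 to 110351909) rose by 1.23 ± 0.17 (edgeR adjusted p = 0.00017) and the microtubule protein Mapt by 2.37 ± 0.44 (edgeR adjusted p = 0.00219). Among genes of at least 10 CPM whose treated libraries all lay beyond the controls, the largest rise was Scg2, which encodes a granule protein of neuroendocrine cells (ENSMUST00000049972, chromosome 1, 79434669 to 79440120), at 3.40 ± 0.60 (edgeR adjusted p = 0.00186), followed by the sorting receptor Sorcs1 at 3.17 ± 0.69 (edgeR adjusted p = 0.0058). Oxidative phosphorylation had 16 genes up and 2 down of 68 (19 and 4 adjusted over the list alone, camera adjusted p = 0.0197, adjusted p = 0.717 with an estimated correlation), among them Cox7b at 0.72 ± 0.13 (edgeR adjusted p = 0.00108). Markers of other cells moved as well. Endothelial markers fell, 10 of 19, with a median of -1.03 (camera adjusted p = 3.2e-08, adjusted p = 0.229 with an estimated correlation) and Plvap at -1.21 ± 0.21 (edgeR adjusted p = 0.000969). Macrophage markers fell, 10 of 20 (camera adjusted p = 2.66e-05, adjusted p = 0.232 with an estimated correlation), and so did erythroid genes, 6 of 7, with globin at 0.151 ± 0.0336% of footprints against 0.842 ± 0.339% in controls (SD, n = 5). Schwann cell markers rose, 3 of 7 (camera adjusted p = 0.0399, adjusted p = 0.232 with an estimated correlation). Fibroblast and pericyte markers had 7 genes down and 2 up of 24 (camera adjusted p = 0.03, adjusted p = 0.664 with an estimated correlation). Markers of kidney, liver, pancreas and muscle fell, 9 of 16 (camera adjusted p = 0.000152, adjusted p = 0.229 with an estimated correlation), with the pancreatic enzymes Ctrb1 at -4.96 ± 1.18 (edgeR adjusted p = 0.0102) and Cpa1 at -4.601 ± 1.102 (edgeR adjusted p = 0.0104). Controls differed widely in the summed footprints of 6 pancreatic genes, with 840 CPM in C5840, 195 CPM in C5696 and 25.3 to 54.2 CPM in the other three, against 26.7 CPM in DFMO mouse D135, and the Cpa1 call was lost without C5840 (-3.08, adjusted p = 0.057).

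In RNA, DFMO alone raised 3132 of 14280 genes and lowered 2506. The neuropeptide gene Vip had no count in any control library and averaged 48.8 CPM under DFMO, a rise put at 1350-fold when 3 counts are allowed over the control group. Of these 4 control libraries 3 were of low complexity, where expressed genes can have no count. Oat, for one, was at 0 CPM in C5781 against 26.95 to 41.96 CPM in the other controls. The fold is therefore not a firm lower bound. Tac1, another neuropeptide gene, rose by 8.24 ± 1.15 (edgeR adjusted p = 8.86e-05) and Scg2 by 5.78 ± 0.65 (edgeR adjusted p = 2.17e-05). Among neuronal genes 28 of 51 rose and 2 fell (29 and 2 adjusted over the list alone, camera adjusted p = 6.08e-05, adjusted p = 0.227 with an estimated correlation), with the adhesion molecule L1cam at 2.73 ± 0.29 (edgeR adjusted p = 1.33e-05). Schwann cell markers rose, 11 of 16 with 1 down (12 and 1 adjusted over the list alone, camera adjusted p = 0.000292, adjusted p = 0.227 with an estimated correlation), with the lineage factor Sox10 at 6.89 ± 0.96 (edgeR adjusted p = 8.86e-05). Endothelial markers fell, 7 of 20 (camera adjusted p = 0.0108, adjusted p = 0.583 with an estimated correlation), and so did erythroid genes, 5 of 9 (camera adjusted p = 0.0183, adjusted p = 0.583 with an estimated correlation). Of 79 ribosomal protein genes 71 fell and 1 rose in RNA (camera adjusted p = 1.37e-22, adjusted p = 0.583 with an estimated correlation), with Rpl22 at -2.42 ± 0.39 (edgeR adjusted p = 0.000282). Their median was -1.68, and -0.59 with 5 down once the 4 low-complexity RNA libraries were left out. Oxidative phosphorylation had 33 genes down and 4 up of 68 in RNA (35 and 5 adjusted over the list alone, camera adjusted p = 5.02e-07, adjusted p = 0.647 with an estimated correlation). Its median was -0.77, and -0.27 with 4 down without those libraries.

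Efficiency under DFMO rose on ribosomal protein genes, with 1783 genes up and 1931 down of 11847. Of 79 ribosomal protein genes 67 rose in efficiency (71 up and 1 down adjusted over the list alone, camera adjusted p = 6.45e-26, adjusted p = 0.734 with an estimated correlation), among them Rpl38 at 3.62 ± 0.73 (edgeR adjusted p = 0.000622). Without the 4 low-complexity RNA libraries 13 rose. Pycr1, the last enzyme of proline synthesis, had lower efficiency at -1.97 ± 0.58 (edgeR adjusted p = 0.0101), which was -1.13 without the low-complexity libraries (adjusted p = 0.0887). With those 4 libraries left out, and so with 1 control RNA library, RNA calls were 2273 instead of 5638 and efficiency calls 1308 instead of 3714. Leaving out the 3 RNA libraries far from their own footprints gave 2576 in RNA and 2461 in efficiency. With limma on RPKM the RNA calls split into 7858 up and 615 down, and the efficiency calls into 394 up and 5768 down.

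The diet alone left no footprint change that passed in edgeR. Of 12095 genes, 0 passed, 1312 had an unadjusted p under 0.05, and the smallest adjusted p was 0.104. DESeq2 called 102 genes and limma on RPKM 30, and leaving out mouse D5747 gave 12 and mouse P5702 gave 17. Several lists nevertheless moved together in footprints. Replication-dependent histones were higher, with 22 of 26 up adjusted over the list alone (camera adjusted p = 1.89e-22, adjusted p = 0.253 with an estimated correlation), although close copies share reads. The unfolded protein response was lower, with 12 of 22 down adjusted over the list alone (median -0.21, camera adjusted p = 1.83e-07, adjusted p = 0.059 with an estimated correlation; fry adjusted p = 0.0117). Interferon response genes were lower, with 6 of 26 down and 1 up adjusted over the list alone (camera adjusted p = 9.64e-06, adjusted p = 0.325 with an estimated correlation). Erythroid genes were higher, 6 of 7 adjusted over the list alone (camera adjusted p = 1.02e-10, adjusted p = 0.059 with an estimated correlation), and globin made up 2.44 ± 1.12% of footprints (SD, n = 5). Markers of kidney, liver, pancreas and muscle were lower, 11 of 16 adjusted over the list alone (camera adjusted p = 3.68e-08, adjusted p = 0.059 with an estimated correlation).

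RNA on the diet alone had 324 genes up and 162 down of 14280, and few members of any list passed. Cholesterol synthesis genes rose, 4 of 24 (7 adjusted over the list alone, camera adjusted p = 0.00469, adjusted p = 0.887 with an estimated correlation). Interferon response genes fell, 3 of 34 (camera adjusted p = 0.000745, adjusted p = 0.887 with an estimated correlation), with the chemokine Cxcl9 at -3.60 ± 1.00 (edgeR adjusted p = 0.049). Markers of macrophages, neutrophils, T and NK cells and B and plasma cells did not pass as lists (camera adjusted p = 0.249, 0.328, 0.249 and 0.119). Single falls included the lipid transfer gene Mttp at -2.95 ± 0.37 (edgeR adjusted p = 0.00138) and the leukocyte gene Lst1 at -2.24 ± 0.41 (edgeR adjusted p = 0.0186). Oxidative phosphorylation genes fell, 5 of 68 (10 adjusted over the list alone, camera adjusted p = 5.74e-13, adjusted p = 0.887 with an estimated correlation). The 486 RNA calls depended on single libraries. They became 7 without the low-complexity libraries, 1 without the 3 RNA libraries unlike their own footprints, 3027 with DESeq2, 974 with RLE scaling and 77 with limma. Leaving out single mice moved them by more than 1.5 times for 17 of 19, all but C5781 and PD5746, from 6 without C5696 to 4511 without P5828.

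Efficiency on the diet alone rose for 120 genes and fell for 444. Oxidative phosphorylation genes rose, 6 of 68 (camera adjusted p = 1.51e-13, adjusted p = 0.966 with an estimated correlation), with Cox7b at 1.50 ± 0.33 (edgeR adjusted p = 0.0174) and Uqcrb at 1.40 ± 0.30 (edgeR adjusted p = 0.0147). Both passed in the 38 libraries that remain without C5840 (adjusted p = 0.0327 and 0.0279), and neither once mice were also a block, at 1.49 (adjusted p = 0.0567) and 1.38 (adjusted p = 0.0513). Ribosomal protein genes rose, 3 of 79 (36 adjusted over the list alone, camera adjusted p = 2.98e-27, adjusted p = 0.966 with an estimated correlation). Of 26 genes of proline and arginine metabolism 3 fell (5 adjusted over the list alone, camera adjusted p = 0.0491, adjusted p = 0.966 with an estimated correlation), among them Aldh18a1 at -1.27 ± 0.37 (edgeR adjusted p = 0.0433) and Pycr1 at -1.91 ± 0.58 (edgeR adjusted p = 0.0483). The list call was lost without C5840 (adjusted p = 0.066), and both gene calls were lost there (adjusted p = 0.0632 and 0.0648) and in most other fits leaving out a single mouse. The total of 564 became 245 without C5840 and 43 once mice were also a block, and without the low-complexity libraries it was 119. The total moved by more than 1.5 times for 14 of 20 mice left out in turn, all but C5781, D5747, PD5732, PD5746, PD5805 and PD5825, from 36 without P5784 to 3073 without P5828. With limma on RPKM the split was 90 up and 2235 down.

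The combination against control gave the widest footprint response, with 2020 genes up and 1878 down of 12095. Within the polyamine pathway, footprints rose on genes that sustain ornithine and S-adenosylmethionine decarboxylation and fell on spermidine synthase and polyamine oxidase. Azin1, the antizyme inhibitor that shields ornithine decarboxylase (ENSMUST00000065308, chromosome 15, 38487427 to 38519266), rose from 24.9 ± 5.43 to 60.5 ± 11.7 CPM (SD, n = 5; log2 1.27 ± 0.20, edgeR adjusted p = 0.000102). Amd1, S-adenosylmethionine decarboxylase (ENSMUST00000238969, absent from the reference copy used here), rose by 1.65 ± 0.41 (edgeR adjusted p = 0.00598) in footprints and 1.37 ± 0.33 (edgeR adjusted p = 0.00355) in RNA. Without the low-complexity libraries, and so with 1 control RNA library, the RNA change of Amd1 was 0.59 and did not pass (adjusted p = 0.184). Odc1, the target of DFMO (ENSMUST00000171737, chromosome 12, 17544794 to 17551505), rose by 0.47 ± 0.15 in footprints (edgeR adjusted p = 0.0237), a call lost without mouse C5812 (adjusted p = 0.0544), PD5736 (adjusted p = 0.0709) or PD5746 (adjusted p = 0.051). Its RNA did not pass (-0.07, edgeR adjusted p = 0.884), with controls spread from 86.4 to 375 CPM around 150 to 263 CPM in the combination. In simulated data the RNA test recovered 4.5% of 2-fold changes, but far fewer genes changed there, so power in the real data may be higher. Without the low-complexity libraries, and so against C5812 alone at 375 CPM, Odc1 RNA was lower (-0.893, adjusted p = 0.0257), so its RNA change stays open. Srm, spermidine synthase (ENSMUST00000006611, chromosome 4, 148591503 to 148594993), fell by 0.49 ± 0.11 (edgeR adjusted p = 0.00148). Paox, which oxidizes acetylated polyamines (ENSMUST00000026537, chromosome 7, 140115799 to 140137224), fell by 1.23 ± 0.17 in footprints (edgeR adjusted p = 2.81e-05) and by 2.23 ± 0.36 in RNA (edgeR adjusted p = 0.000269). Without the low-complexity libraries, and so against C5812 alone, its RNA fall was smaller but still passed (-1.513, adjusted p = 0.00102). Sms, Smox, Sat1, Oaz1 and Eif5a did not pass in footprints. The polyamine list as a whole had 6 genes up and 4 down of 22 (camera adjusted p = 0.64). Under DFMO alone Azin1 averaged 57.7 ± 17.1 CPM and Amd1 149 ± 108 CPM, and on the diet alone 21.8 ± 4.45 and 35.1 ± 7.58 CPM (SD, n = 5). Odc1 differed from these, with footprints of 507.7 to 650.5 CPM on the diet alone, above all controls (438.1 to 497.7 CPM), though without a call. Its footprints ran from 379.4 to 883.3 CPM under DFMO alone and from 522 to 756.6 CPM in the combination.

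**Figure D2:**
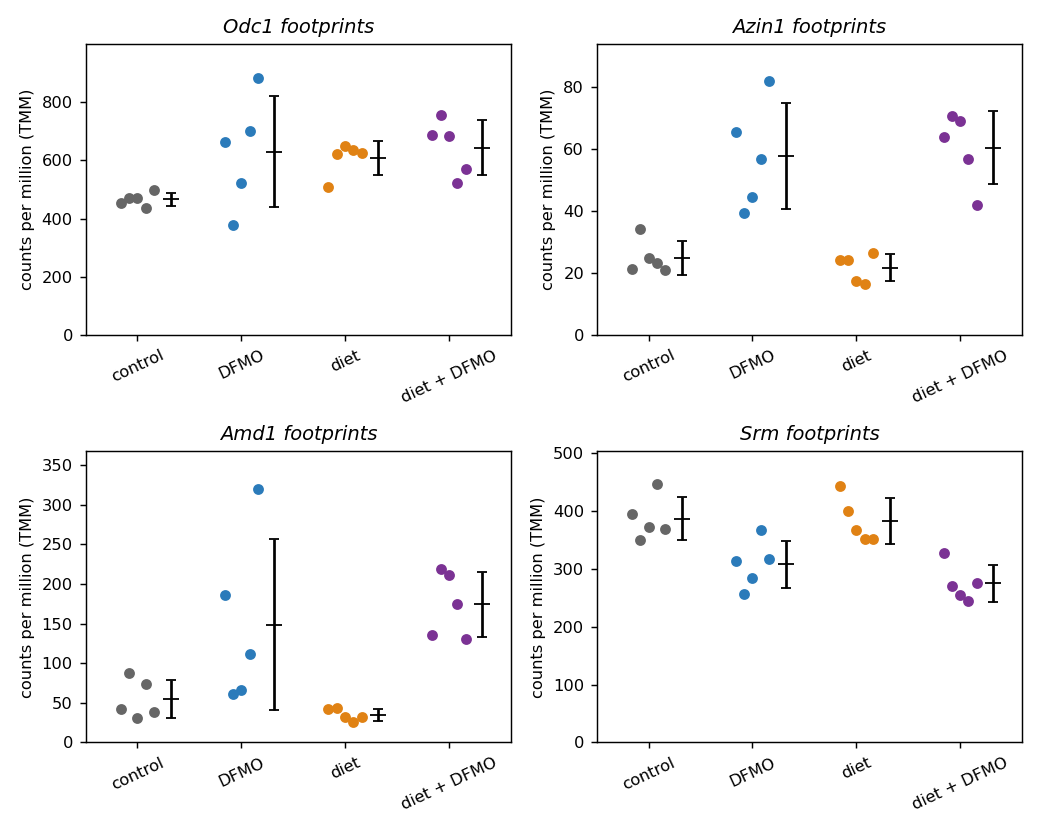
Footprint CPM of Odc1, Azin1, Amd1 and Srm in the 4 groups. Each point is a mouse, and bars give mean ± SD.

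MYC targets in ribosome biogenesis fell broadly in footprints of the combination, 37 of 48 with 1 up, also when adjusted over the list alone (median -0.53, camera adjusted p = 1.34e-16, adjusted p = 0.275 with an estimated correlation; fry adjusted p = 2.86e-05). Ddx21 changed by -1.08 ± 0.15 (edgeR adjusted p = 2.09e-05), the processome gene Rrp12 by -0.83 ± 0.12 (edgeR adjusted p = 3.53e-05) and the large-subunit assembly factor Pes1 by -0.74 ± 0.10 (edgeR adjusted p = 2.61e-05). Translation factors fell, 20 of 46 with 4 up (21 and 4 adjusted over the list alone, camera adjusted p = 5.63e-05, adjusted p = 0.827 with an estimated correlation), with the subunit-joining factor Eif5b at -0.81 ± 0.12 (edgeR adjusted p = 6.26e-05) and Eif3b at -0.68 ± 0.09 (edgeR adjusted p = 2.11e-05). Mycn itself (ENSMUST00000043396, chromosome 12, 12936093 to 12941914) was at 291 ± 41.5 CPM in footprints against 350 ± 42.9 CPM in controls (SD, n = 5; -0.27 ± 0.10, edgeR adjusted p = 0.0466). The Mycn call was lost when any of mice C5696, C5781, C5812, C5840, D135, D5802, D5806, P5705, P5785, P5828, PD5736, PD5746, PD5805 and PD5825 was left out, with adjusted p = 0.0505 to 0.137. Reads of the human transgene that align to the mouse gene cannot be told apart in these counts. The proline synthesis gene Aldh18a1 fell by 0.49 ± 0.14 (edgeR adjusted p = 0.00879), while Pycr1, Oat, Arg2 and Asns did not pass.

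Cell cycle genes fell in footprints of the combination. Of 60 mitosis and G2/M genes 21 fell (23 adjusted over the list alone; median -0.36, camera adjusted p = 6.85e-06, adjusted p = 0.876 with an estimated correlation). The spindle kinase Aurka changed by -0.80 ± 0.17 (edgeR adjusted p = 0.00105), its activator Tpx2 by -0.86 ± 0.18 (edgeR adjusted p = 0.0011) and the survivin gene Birc5 by -0.58 ± 0.15 (edgeR adjusted p = 0.00457). Of 52 S phase genes 23 fell and 3 rose (27 and 3 adjusted over the list alone, camera adjusted p = 7.22e-06, adjusted p = 0.876 with an estimated correlation). Thymidylate synthase Tyms changed by -0.85 ± 0.15 (edgeR adjusted p = 0.000268) and the ribonucleotide reductase subunit Rrm2 by -0.70 ± 0.14 (edgeR adjusted p = 0.000804). Neuronal genes rose, 22 of 50 with 5 down (26 and 7 adjusted over the list alone; median 0.46, camera adjusted p = 9.52e-05, adjusted p = 0.827 with an estimated correlation; fry adjusted p = 0.0132). Gfra2 rose by 3.06 ± 0.34 (edgeR adjusted p = 4.65e-06), Elavl4 by 1.69 ± 0.17 (edgeR adjusted p = 1.6e-06) and the synaptic vesicle gene Syn1 by 1.04 ± 0.14 (edgeR adjusted p = 2.1e-05). Oxidative phosphorylation rose, 23 of 68 with 5 down (camera adjusted p = 0.00272, adjusted p = 0.876 with an estimated correlation), with Cox7b at 1.08 ± 0.13 (edgeR adjusted p = 5.68e-06).

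Single genes named here had at least 10 CPM and all combination libraries beyond all controls. Scg2 rose by 4.16 ± 0.60 (edgeR adjusted p = 0.000114), the transcription factor Etv1 by 3.88 ± 0.74 (edgeR adjusted p = 0.000979) and the zinc finger gene Bnc2 by 3.38 ± 0.43 (edgeR adjusted p = 2.55e-05). The synaptic pentraxin Nptx2 fell from 65.0 ± 12.1 to 7.61 ± 2.02 CPM (SD, n = 5; -3.09 ± 0.24, edgeR adjusted p = 5.66e-08), the phosphatase inhibitor gene Ppp1r14a changed by -2.68 ± 0.21 (edgeR adjusted p = 4.8e-08) and the Wnt receptor Fzd2 by -2.54 ± 0.36 (edgeR adjusted p = 5.52e-05). Markers of other cells moved in the same libraries. Macrophage markers fell, 12 of 20 (camera adjusted p = 2.59e-05, adjusted p = 0.677 with an estimated correlation), with complement C1qb at -0.67 ± 0.10 (edgeR adjusted p = 6.84e-05). Endothelial markers fell, 9 of 19 (camera adjusted p = 0.00177, adjusted p = 0.876 with an estimated correlation), and Schwann cell markers rose, 4 of 7 (camera adjusted p = 0.0327, adjusted p = 0.58 with an estimated correlation). The unfolded protein response had 9 genes down and 3 up of 22 (camera adjusted p = 0.0327, adjusted p = 0.827 with an estimated correlation), with Manf at -0.88 ± 0.13 (edgeR adjusted p = 3.61e-05). ATF4 targets (10 down and 2 up of 36, camera adjusted p = 0.224), noradrenergic identity (8 up and 8 down of 28, camera adjusted p = 0.897) and p53 targets (6 down and 4 up of 22, camera adjusted p = 0.94) did not move as lists.

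**Figure D3:**
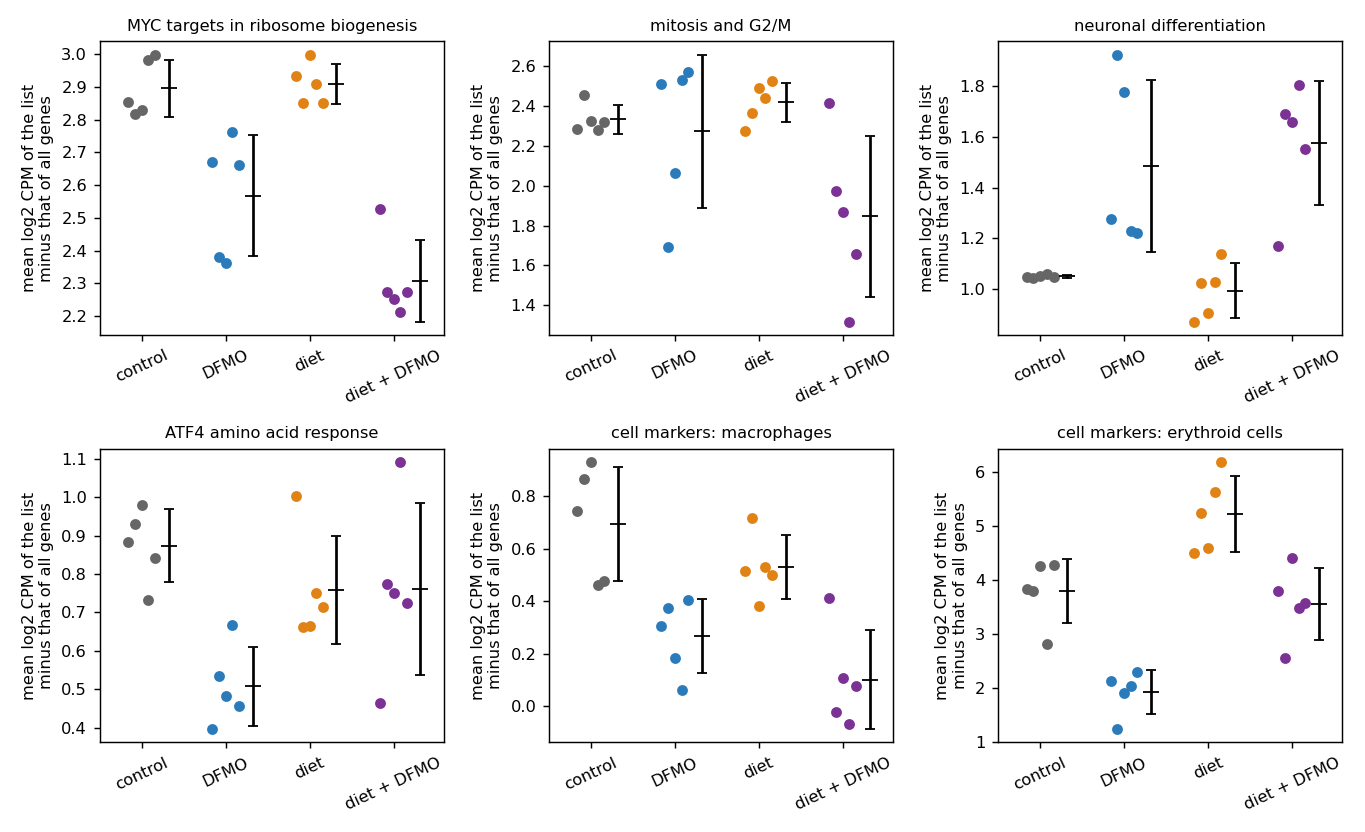
Footprint scores of 6 gene lists, as mean log2 CPM of the list minus that of all genes, in the 4 groups. Each point is a mouse, and bars give mean ± SD.

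RNA in the combination had 3298 genes up and 2529 down of 14280. Neuronal genes rose, 26 of 51 with 5 down (camera adjusted p = 0.00152, adjusted p = 0.545 with an estimated correlation), with the neurofilament gene Prph at 4.45 ± 0.52 (edgeR adjusted p = 1.42e-05). Markers of other cells did not pass as lists with camera but moved as well. Of 16 Schwann cell markers 7 rose and 2 fell (camera adjusted p = 0.216, fry adjusted p = 0.000383), with scores of -4.384 ± 0.191 in controls (SD, n = 4) and -3.436 ± 0.283 in the combination (SD, n = 5) that did not overlap. Of 24 fibroblast and pericyte markers 11 rose and 2 fell (camera adjusted p = 0.0956, fry adjusted p = 0.0205). The macrophage score was 1.392 ± 0.027 in controls (SD, n = 4) and 0.953 ± 0.290 in the combination (SD, n = 5), also without overlap, with 4 of 20 genes down and 1 up (camera adjusted p = 0.433). Tac1 rose by 10.30 ± 1.18 (edgeR adjusted p = 1.42e-05). The peptide hormone gene Ostn had no count in controls, and its rise was put at 1170-fold and that of Vip at 274-fold, with 3 counts allowed over the control group. These folds are no firm lower bounds either, since most control RNA libraries were of low complexity. Mitosis and G2/M genes fell, 33 of 60 (camera adjusted p = 1.03e-07, adjusted p = 0.915 with an estimated correlation), with the kinetochore motor Cenpe at -2.80 and the ubiquitin-conjugating enzyme gene Ube2c at -1.95. Proline and arginine metabolism rose in RNA, 11 of 27 (12 adjusted over the list alone, camera adjusted p = 0.0313, adjusted p = 0.915 with an estimated correlation), with Aldh18a1 at 1.30 ± 0.36 (edgeR adjusted p = 0.00828) and Pycr1 at 1.76 ± 0.59 (edgeR adjusted p = 0.0223). Mycn RNA rose by 0.91 ± 0.26 (edgeR adjusted p = 0.0107). Ribosomal protein genes fell, 68 of 79 with 1 up (camera adjusted p = 1.42e-17, adjusted p = 0.915 with an estimated correlation), but 0 passed without the 4 low-complexity RNA libraries, where their median was -0.39 instead of -1.39. With the 1 control RNA library left there, Aldh18a1 was at 0.30 (adjusted p = 0.434) and Pycr1 at 0.81 (adjusted p = 0.177).

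Efficiency in the combination rose for 1628 genes and fell for 1660. Of 26 genes of proline and arginine metabolism 9 lost efficiency (camera adjusted p = 0.00853, adjusted p = 0.912 with an estimated correlation), among them Pycr1 at -2.09 ± 0.58 (edgeR adjusted p = 0.0085) and Aldh18a1 at -1.71 ± 0.37 (edgeR adjusted p = 0.00168). Mycn lost efficiency (-1.09 ± 0.28, edgeR adjusted p = 0.00488) and the acetyltransferase Sat1 gained it (0.94 ± 0.31, edgeR adjusted p = 0.0207). ATF4 targets fell, 12 of 36 with 3 up (camera adjusted p = 0.0377, adjusted p = 0.912 with an estimated correlation), with the amino acid transporter Slc7a5 at -3.78 ± 0.74 (edgeR adjusted p = 0.000751). Ribosomal protein genes rose, 61 of 79 (68 up and 1 down adjusted over the list alone, camera adjusted p = 1.54e-19, adjusted p = 0.912 with an estimated correlation), and 0 rose without the 4 low-complexity libraries. Without those libraries RNA calls were 2369 and efficiency calls 658, against 5827 and 3288. Efficiency calls were 2049 without mouse C5778. With limma on RPKM the split was 7308 up and 727 down in RNA, and 487 up and 4658 down in efficiency. Against the 1 control RNA library left in that fit, efficiency changes of Pycr1, Aldh18a1 and Sat1 were -1.28, -0.82 and 0.77 and did not pass (adjusted p = 0.0785, 0.0923 and 0.187). The Sat1 call was also lost without the 3 unmatched RNA libraries (adjusted p = 0.06) and without mouse PD5746 (adjusted p = 0.0671), PD5805 (adjusted p = 0.0508) or PD5825 (adjusted p = 0.0504).

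Against DFMO alone, footprints of the combination were lower on cell division genes as a list and higher on ATF4 targets and on markers of other tissues, with 275 genes up and 115 down. Mitosis and G2/M genes were lower as a list (2 of 60 passed, median -0.36, camera adjusted p = 2.6e-15, adjusted p = 0.597 with an estimated correlation). Their score was 1.85 ± 0.404 in the combination and 2.27 ± 0.384 under DFMO alone (SD, n = 5), with overlapping ranges, against 2.33 ± 0.072 in controls. Aurka averaged 43.2 ± 13.9 CPM against 67.8 ± 12.7 CPM under DFMO alone (SD, n = 5; -0.65 ± 0.16, edgeR adjusted p = 0.03). MYC targets in ribosome biogenesis (median -0.21, camera adjusted p = 2.21e-09, adjusted p = 0.342 with an estimated correlation) and S phase genes (camera adjusted p = 1.54e-08, adjusted p = 0.597 with an estimated correlation) were lower too, with 1 gene passing in each, Nhp2 at -0.54 ± 0.10 (edgeR adjusted p = 0.00586) and Rrm2 at -0.55 ± 0.14 (edgeR adjusted p = 0.0334). ATF4 targets rose, 6 of 36 with 1 down (11 and 2 adjusted over the list alone, camera adjusted p = 0.00269, adjusted p = 0.597 with an estimated correlation). Phgdh, the entry enzyme of serine synthesis, rose by 1.64 ± 0.38 (edgeR adjusted p = 0.0268) and the stress regulator Nupr1 by 1.67 ± 0.37 (edgeR adjusted p = 0.0159). Adrenal cortex genes rose, 4 of 10 (9 adjusted over the list alone, camera adjusted p = 1.35e-08, adjusted p = 0.292 with an estimated correlation), with the steroid hydroxylase Cyp11b1 at 3.13 ± 0.58 (edgeR adjusted p = 0.00902). Erythroid genes rose, 5 of 7 (camera adjusted p = 1.54e-09, adjusted p = 0.187 with an estimated correlation), as did markers of kidney, liver, pancreas and muscle, 6 of 16 (camera adjusted p = 6.57e-05, adjusted p = 0.292 with an estimated correlation), with Cpa1 at 5.91 ± 1.06 (edgeR adjusted p = 0.0105). The count of 390 depended on single mice. It was 632 without D5747, 1152 without PD5732, 158 without D5806, 228 without PD5746, 123 without PD5805 and 151 without PD5825. It was 684 with DESeq2, and limma on RPKM called 156 up and 31 down.

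In RNA the combination had 438 genes up and 295 down against DFMO alone. Schwann cell markers fell, 9 of 16 with 1 up (10 and 4 adjusted over the list alone), and this list kept its call with an estimated correlation (camera adjusted p = 2.74e-08, adjusted p = 0.0337 with an estimated correlation). The glial lipid carrier Fabp7 changed by -4.60 ± 0.73 (edgeR adjusted p = 0.00053) and Sox10 by -3.18 ± 0.55 (edgeR adjusted p = 0.000983). Footprints, where fewer of these markers were measured, showed no such fall, with scores of -1.741 ± 0.681 under DFMO and -1.726 ± 0.358 in the combination (SD, n = 5). The RNA libraries compared here include D135, D5823 and PD5732, which were unlike the footprints of their own mice. Markers of kidney, liver, pancreas and muscle rose, 10 of 15 (camera adjusted p = 2.76e-10, adjusted p = 0.0785 with an estimated correlation), as did erythroid genes, 3 of 9 (camera adjusted p = 1.54e-05, adjusted p = 0.209 with an estimated correlation). ATF4 targets rose, 4 of 39 (7 adjusted over the list alone, camera adjusted p = 0.000299, adjusted p = 0.398 with an estimated correlation; fry adjusted p = 0.0246), with the stress hormone Fgf21 at 4.58 ± 0.70 (edgeR adjusted p = 0.000319). Noradrenergic identity had 5 genes up and 4 down of 29, with the dopa decarboxylase gene Ddc at -1.20 ± 0.27. Ostn rose by 12.48 ± 1.44. The 733 RNA calls became 3450 without the low-complexity libraries, 89 without the 3 unmatched ones and 1440 with DESeq2. Single mice moved them to 1320 without C5781, 430 without D135, 440 without D5747, 426 without D5823, 1110 without P5828, 430 without PD5732 and 454 without PD5805. With limma on RPKM the split was 454 up and 489 down. In efficiency edgeR called 0 of 11847 genes, with 371 at an unadjusted p under 0.05, and DESeq2 called 11 and limma 1. Leaving out any mouse but D135, D5823, PD5732, PD5805 and PD5825 gave 1 to 3 calls, with 3 without C5840, whether or not mice were also a block.

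Adding DFMO to the diet lowered footprints on ribosome biogenesis, S phase and mitosis genes and raised them on neuronal genes, while markers of several other cells moved too, with 1792 genes up and 1697 down against the diet alone. MYC targets in ribosome biogenesis fell, 38 of 48 (43 adjusted over the list alone; median -0.49, camera adjusted p = 6.36e-20, adjusted p = 0.141 with an estimated correlation), with the processome gene Bysl at -0.78 ± 0.10 (edgeR adjusted p = 2.8e-05) and Dcaf13 at -0.90 ± 0.12 (edgeR adjusted p = 2.94e-05). S phase genes fell, 29 of 52 with 1 up (36 and 1 adjusted over the list alone, camera adjusted p = 6.04e-10, adjusted p = 0.666 with an estimated correlation), with Tyms at -0.75 ± 0.15 (edgeR adjusted p = 0.00102). Mitosis and G2/M genes fell, 27 of 60 (31 adjusted over the list alone, camera adjusted p = 6.04e-10, adjusted p = 0.666 with an estimated correlation), with Birc5 at -0.81 ± 0.14 (edgeR adjusted p = 0.000436). Ribosomal protein genes fell, 16 of 79 (15 adjusted over the list alone, camera adjusted p = 0.000221, adjusted p = 0.749 with an estimated correlation), with Rpl19 at -0.60 ± 0.10 (edgeR adjusted p = 0.000376). Cholesterol synthesis fell, 8 of 24 with 1 up (camera adjusted p = 0.0447, adjusted p = 0.666 with an estimated correlation). Neuronal genes rose, 23 of 50 with 1 down (24 and 2 adjusted over the list alone, camera adjusted p = 1.69e-06, adjusted p = 0.632 with an estimated correlation), with Elavl4 at 1.63 ± 0.17 (edgeR adjusted p = 3.27e-06) and Gfra2 at 2.77 ± 0.31 (edgeR adjusted p = 8.99e-06). Nptx2 changed by -3.06 ± 0.23 (edgeR adjusted p = 1.14e-07) and Ppp1r14a by -2.37 ± 0.21 (edgeR adjusted p = 2.32e-07). Erythroid genes fell, 6 of 7 (camera adjusted p = 0.000524, adjusted p = 0.632 with an estimated correlation). Schwann cell markers rose, 3 of 7 (camera adjusted p = 0.0246, adjusted p = 0.575 with an estimated correlation), with scores of -2.742 ± 0.170 on the diet and -1.726 ± 0.358 in the combination (SD, n = 5) that did not overlap. Markers of kidney, liver, pancreas and muscle had 6 genes up and 1 down of 16 (camera adjusted p = 0.0419, adjusted p = 0.666 with an estimated correlation), and their scores did not overlap either (-1.922 ± 0.636 and -0.043 ± 0.607, SD, n = 5). Endothelial markers fell, 4 of 19, macrophage markers, 6 of 20, and fibroblast and pericyte markers, 4 of 24 (camera adjusted p = 0.00263, 0.00437 and 0.0246, each adjusted p = 0.666 with an estimated correlation). A change in the cells making up the tumor pieces is thus not set apart from a change within tumor cells. With limma on RPKM the split was 2645 up and 803 down.

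RNA of the combination had 1289 genes up and 1239 down against the diet alone. Mitosis and G2/M genes fell, 25 of 60 (30 adjusted over the list alone, camera adjusted p = 2.01e-10, adjusted p = 0.365 with an estimated correlation), and so did S phase genes, 25 of 52 (camera adjusted p = 2.08e-09, adjusted p = 0.353 with an estimated correlation), with the chromatin assembly gene Chaf1a at -1.32. Neuronal genes rose, 19 of 51 with 1 down (camera adjusted p = 0.00028, adjusted p = 0.353 with an estimated correlation). Schwann cell markers rose with them, 5 of 16 with 1 down (camera adjusted p = 0.0175, adjusted p = 0.365 with an estimated correlation), from a score of -4.388 ± 0.249 to -3.436 ± 0.283 without overlap (SD, n = 5), and endothelial markers fell, 3 of 20 (camera adjusted p = 0.00677, adjusted p = 0.617 with an estimated correlation). Ostn had no count on the diet alone and rose at least 2020-fold with 3 counts allowed over that group, and Tac1 rose by 7.79 ± 0.85 (edgeR adjusted p = 1.48e-05). RNA calls went from 2528 to 5424 without the low-complexity libraries, 1004 without the 3 unmatched ones, 4046 without mouse C5781, 1614 without PD5732 and 1447 without PD5805. RLE scaling gave 1530 up and 865 down, and limma on RPKM 1637 up and 443 down. In efficiency 84 genes rose and 13 fell. Cacna2d1, a calcium channel subunit, rose by 2.56 ± 0.51 (edgeR adjusted p = 0.00501), and the ribosome assembly ATPase Mdn1 fell by 1.33 ± 0.29 (edgeR adjusted p = 0.0163). Polyamine genes rose, 2 of 21 (6 adjusted over the list alone, camera adjusted p = 0.027, adjusted p = 0.87 with an estimated correlation). These were Amd1 at 1.86 ± 0.48 (edgeR adjusted p = 0.049), lost in most fits leaving out a single mouse and without the 3 unmatched libraries (adjusted p = 0.137), and the polyamine transporter Atp13a3 at 1.26 ± 0.30 (edgeR adjusted p = 0.0248). The 97 efficiency calls became 87 without C5840 and 44 once mice were also a block, 603 without the low-complexity libraries, 40 without the 3 unmatched ones and 265 with DESeq2, and RLE scaling gave 63 up and 25 down. They became 289 without C5781, 188 without P5705, 44 without P5785, 56 without P5828, 41 without PD5732, 43 without PD5736 and 46 without PD5805.

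The interaction asks where the combination departs from the sum of diet and DFMO, and in footprints 42 genes lay above that sum and 3 below. Pancreatic carboxypeptidase Cpa1 was at 10.36 ± 1.58 (edgeR adjusted p = 0.0143), and the markers of kidney, liver, pancreas and muscle rose, 6 of 16, a call kept with an estimated correlation (camera adjusted p = 1.81e-13, adjusted p = 0.015 with an estimated correlation). Below the sum lay the microRNA processor Dicer1 at -0.78 ± 0.16 (edgeR adjusted p = 0.0202), the zinc finger gene Zfp503 at -1.08 ± 0.22 (edgeR adjusted p = 0.022) and the snoRNP gene Nhp2 at -0.68 ± 0.14 (edgeR adjusted p = 0.022). Mitosis genes lay below the sum as a list, with 0 of 60 passing (median -0.43, camera adjusted p = 2e-14, adjusted p = 0.447 with an estimated correlation). The unfolded protein response lay above it, with 6 of 22 up adjusted over the list alone (camera adjusted p = 1.33e-06, adjusted p = 0.15 with an estimated correlation; fry adjusted p = 0.00699). The 45 footprint calls became 25 without mouse C5840, 24 without P5785, 210 without PD5732 and 127 with DESeq2. In RNA 348 genes passed upward and 500 downward. Mttp was at 4.34 ± 0.51 (edgeR adjusted p = 0.000174), the glial gene Apod at -5.68 ± 0.86 (edgeR adjusted p = 0.00239), Sox10 at -5.52 ± 1.23 (edgeR adjusted p = 0.015) and the licensing factor Cdt1 at -2.73 ± 0.48 (edgeR adjusted p = 0.00467). The 848 RNA calls became 9 without the 3 unmatched libraries and 2398 with DESeq2, and 18 of 19 mice, all but PD5746, moved them, from 341 without D135 to 3231 without P5828. Limma on RPKM gave 226 up and 1020 down. In efficiency 34 genes passed upward and 8 downward, with Uqcrb at -2.31 ± 0.42 (edgeR adjusted p = 0.012). These 42 became 15 without C5840 and 14 once mice were also a block, and each of the 20 mice moved them, from 2 without P5784 to 1667 without P5828. RLE scaling gave 166 up and 87 down, and limma on RPKM 416 up and 23 down. The median over all genes was -0.20 in RNA and 0.21 in efficiency.

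In footprints under DFMO, scores for the third base of codons had an exact p under 0.05 for each of the 4 bases before adjustment. A shift particular to codons ending in A is therefore not shown, and none of the 4 passed once adjusted over all 63 scores. Among 11560 genes, the A-ending score, set beforehand as the main one, is the mean log2 CPM of those with an A-ending share of at least 0.244 minus that of those at or below 0.130. It was compared by an exact two-sided permutation of mice and adjusted over 9 comparisons. Across these genes the A-ending share falls as GC content rises (r = -0.802), so the score also follows base composition. In footprints it rose by 0.272 under DFMO (from -0.0951 ± 0.137 to 0.177 ± 0.131, SD, n = 5; exact p = 0.0238, adjusted p = 0.0429), with control C5778 at 0.129 inside the DFMO range of 0.0506 to 0.354. The same score for G-ending codons fell by 0.316 (exact p = 0.00794), with controls at 0.122 to 0.468 and DFMO mice at -0.0791 to 0.104, and also fell in the combination (-0.312, exact p = 0.0238). Under DFMO that for T-ending codons rose by 0.225 (exact p = 0.0238) and that for C-ending codons fell by 0.182 (exact p = 0.0476). Adjusted over all 63 scores against control, these were at 0.0741 for A, 0.0625 for G, 0.0741 for T and 0.1 for C. The A-ending score did not pass on the diet (0.0935, exact p = 0.365) or in the combination (0.119, exact p = 0.23). In RNA it fell by 0.695 under DFMO (exact p = 0.0159, adjusted p = 0.0357) and by 0.583 in the combination (exact p = 0.0159, adjusted p = 0.0357). The low-complexity control libraries scored 0.570 to 0.774 and diet mouse P5828 0.651, but the complex control library C5812 also scored 0.553. In efficiency it rose by 0.968 under DFMO, 0.630 on the diet and 0.703 in the combination. The smallest exact p possible is 0.00794 with 5 mice a side and 0.0159 with 4 controls. Proline codons in footprints did not separate the groups against control (-0.0615 under DFMO, 0.0343 on the diet and -0.0609 in the combination; exact p = 0.318, 0.603 and 0.191). Arginine codons in footprints scored -0.109 under DFMO, 0.0232 on the diet and -0.182 in the combination against control (exact p = 0.0714, 0.698 and 0.0238), the last at 0.0741 adjusted over all 63. None of the 63 scores against control passed once adjusted over all of them. With so few mice a lone score at the smallest possible p could not pass that adjustment, so this failure does not decide against a shift.

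**Figure D4:**
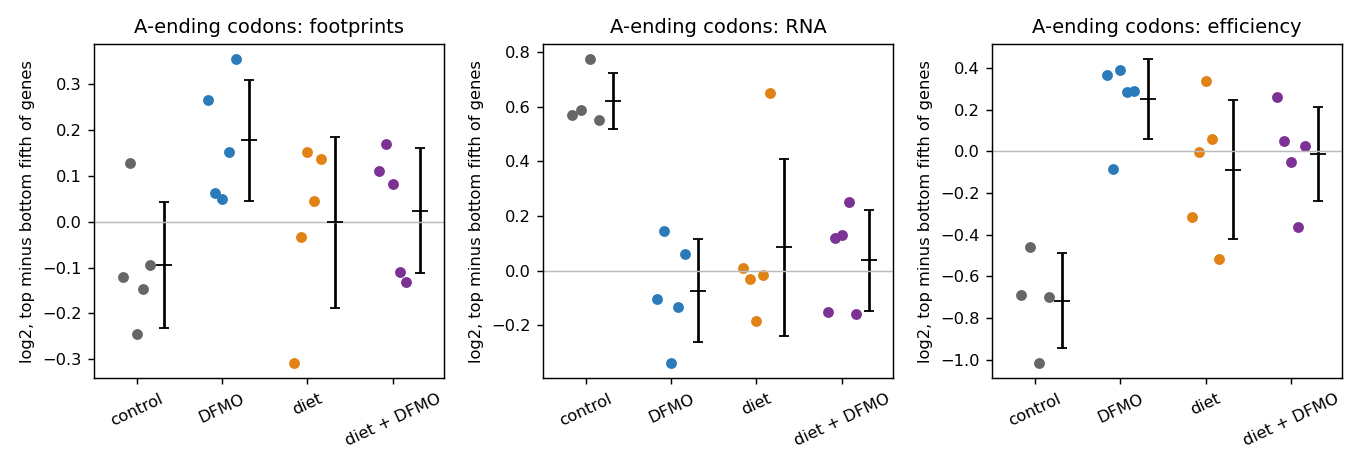
Score of A-ending codons in footprints, RNA and efficiency for the 4 groups. Each point is a mouse, and bars give mean ± SD.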

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

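In each comparison the same mice were also divided into other groups of the same sizes, a test planned before the data were seen. The explanations of the 3 RNA libraries and of mice D5747 and PD5732 below were chosen after seeing the results, as was the test of RNA complexity on the diet, while the test on the combination was set before. Chance is less likely where only the real division, 1 of 40 or 1 of 25, called as many genes. These shares, 0.025 and 0.04, are the smallest that so many divisions allow, and they are not adjusted over the comparisons. This held for footprints under DFMO (2186 calls, at most 3 in other divisions), in the combination (3898, at most 1777) and in the combination against the diet (3489, at most 1789). It held in RNA for DFMO (5638, at most 923), the combination (5827, at most 1525), the combination against DFMO (733, at most 12) and against the diet (2528, at most 75). It held in efficiency for DFMO (3714, at most 726), the combination (3288, at most 720), the combination against the diet (97, at most 0) and the interaction (42, at most 1). These divisions count every RNA library as a separate mouse. The 3 RNA libraries may hold RNA of several mice, as described below, and would then not be independent of the others. In that case the divisions cannot decide on chance in RNA or efficiency where these libraries enter. Without them the RNA calls of the combination against DFMO were far fewer, as given below, with fewer mice left.

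Footprints on the diet and efficiency of the combination against DFMO had 0 calls, which all 40 and all 25 divisions reach by construction (at most 1 and 0 elsewhere), so the divisions say nothing there. For the rest the divisions leave chance open. The RNA of the diet (486) was reached by 5 of 40 divisions, the real one included, with 6873 calls when control C5812 and diet mouse P5828 changed places, a division that follows RNA complexity rather than diet. Its efficiency (564) was reached by 2 of 25, with at most 749 elsewhere. The RNA interaction (848) was reached by 2 of 40, with at most 2915, and the footprint interaction (45) by 2 of 40, with at most 49. Footprints of the combination against DFMO (390) were reached by 5 of 40, and the division that exchanged only mice D5747 and PD5732 called 2064, which points to structure other than treatment among these 10 mice.

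RNA and efficiency calls against control rest on 4 control RNA libraries of which 3 were of low complexity. Across genes, the RNA change correlated with the contrast of complex and low-complexity libraries within the diet group, at r = 0.479 in the combination, 0.472 under DFMO and 0.436 on the diet, which is what a technical loss of complexity in the controls would give. The RNA change correlated with the footprint change of the same comparison, as a real response would, at r = 0.513 in the combination, 0.336 under DFMO and 0.039 on the diet. Both explanations therefore stay open for the combination and DFMO, where both could act together, while on the diet low complexity stays open and the values argue against a response carried into footprints. Genes are not independent replicates, so these correlations carry no p value here.

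RNA of DFMO mice D135 and D5823 and of combination mouse PD5732 did not resemble the footprints of its own mouse. A swap of labels is ruled out in its simple form, since 0 pairs of RNA libraries matched the footprints of each other best. RNA of several mice mixed in these libraries remains possible. Y-linked genes, kept out of the fit, stood at 0.937 of the level of the best mixture of other mice in the library farthest from 1. Other RNA libraries also lay near their mixture, such as PD5746 (42.4 against 44.2 CPM) and P5785 (54.2 against 48.8 CPM). Some lay far from it, such as D5747 (0.85 against 14.8 CPM). Mice of like Y-linked level give such closeness without mixing, so it does not by itself show mixing. The RNA of D135 and D5823 lay closest to the footprints of D5747 (r = 0.582 and 0.643), and that of PD5732 to the footprints of PD5805 (r = 0.713).

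Footprints of DFMO mouse D5747 and combination mouse PD5732 lay between both DFMO groups, with a distance to the other group of 1.01 and 0.906 times that to their own, against 1.24 to 1.84 for the other 8 mice, which by itself did not decide on a swap. Globin, taken up after that first test had left it undecided, argues against a swap of these libraries, since its log2 share lay 2.91 SD from the other combination mice in D5747 and 29.2 SD from the other DFMO mice in PD5732, each on the side of its label. Pancreatic footprints also followed the labels (7.44 CPM in D5747 and 1090 CPM in PD5732), and the RNA of D5747 matched its own footprints best (r = 0.747). Both mice had few Y-linked footprints, but so had DFMO mice D135 and D5823 (11.2 and 17.4 CPM, under the limit of 20 CPM). Control C5812 and diet mouse P5702 were the only others (8.13 and 8.7 CPM), so mice with few Y-linked footprints were more frequent under DFMO. In RNA these genes stood at 0.85 CPM in D5747, 1.83 CPM in C5812 and 2.69 CPM in P5702. They stood higher in the RNA libraries that may be mixed, at 15 CPM in D5823, 19.8 CPM in D135 and 34 CPM in PD5732. RNA and footprints of PD5732 thus disagree on its sex, which was read here from footprints alone. An effect of sex alike in all groups does not explain the place of D5747 and PD5732. With it taken out, a test that replaced an earlier one by exchanging these mice, the ratios were 1.01 and 1.05. Sex as a covariate moved the calls between the DFMO groups from 390 to 155, so a part of sex in that count stays open, and what sets these mice apart is not known.

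Single mice stood apart from the other mice of their group in 23 of 196 groups of values tested, where chance alone gives 1 in 20. These are not independent, since the same library can stand apart in many of them. Diet mouse P5828, of low RNA complexity, had the fewest transcripts in its RNA group, at 12970, and its globin share of 12.14% stood out too. Under DFMO the lowest footprint total was 5.128 M, and a globin share of 0.092% stood apart. In diet RNA the same mouse, P5828, stood apart for Aldh18a1 (23.06 CPM), Ddit3 (74.73 CPM), Eif5a (296.8 CPM), Oaz1 (2166 CPM), Paox (51.27 CPM) and Srm (147.9 CPM). In diet footprints single mice stood apart for Asns (206.1 CPM), Ddit3 (2.589 CPM), Oaz1 (271.8 CPM) and Odc1 (507.7 CPM). In control footprints this held for Asns (134.5 CPM), Azin1 (34.26 CPM) and Oaz1 (263 CPM), and in combination footprints for Ddit3 (5.88 CPM). The A-ending codon score stood apart in control RNA (0.7738), diet RNA (0.6507, again P5828) and DFMO efficiency (-0.08339). The score of MYC targets in ribosome biogenesis did in combination footprints (2.526), as did that of mitosis genes in control footprints (2.454).

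The interaction of diet and DFMO called 848 genes in RNA, 45 in footprints and 42 in efficiency, with chance left open as described above. In RNA these were led by Mttp (4.343), S100a10 (3.617) and Cited1 (3.381) above the sum and Apod (-5.685), Fabp7 (-5.223) and Mgat5b (-4.409) below it. In footprints they were Try4 (11.789), Try10 (11.446) and Cpa1 (10.36) above and Zfp503 (-1.085), Dicer1 (-0.784) and Nhp2 (-0.677) below. In efficiency they were Amy1 (10.97), Amy2a5 (8.984) and Cela1 (5.584) above and Uqcrb (-2.31), Filip1l (-2.167) and Hmgn3 (-2.156) below. Reads of the trypsin and amylase copies are shared, so single members of these families are uncertain.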

How the results depend on the processing

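Fits without named libraries, with sex or with thinned footprints were chosen after seeing the results, and the others before the data were examined. Footprint results held best. Of 233 named gene results in footprints DESeq2 kept 233, RLE scaling 232 and limma on RPKM 214. Of 155 in efficiency, 72 held without the 4 low-complexity RNA libraries, which leave 1 control RNA library. With an estimated correlation camera lost 79 of 80 list calls in footprints, 53 of 54 in RNA and 45 of 45 in efficiency, and fry lost 44, 27 and 31. Where a direction turned or a count moved, the cause was not tested.

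Directions turned for Ddit3 RNA in the combination with limma (0.83 against -0.09), and in efficiency under DFMO for Mphosph10 with limma (-0.035), for H1f3 without the low-complexity libraries (-0.16) and without all 7 (-0.076), and for H3c3 without all 7 (-0.012). Replication-dependent histones turned in efficiency without the low-complexity libraries, to -0.66 under DFMO, -0.65 on the diet and -0.94 in the combination. Relative to all genes their RNA scored only -1.449 ± 1.119 in controls (SD, n = 4) and -2.470 ± 0.475 in the combination (SD, n = 5). Their footprints scored 7.487 ± 0.195 and 7.507 ± 0.354 (SD, n = 5). Efficiency of this list, to which H1f3 and H3c3 belong, is thus a ratio to low RNA, and its direction is uncertain.

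RNA calls under DFMO were 8473 with limma, 2273 without the low-complexity libraries, 2576 without the unmatched, 477 without all 7 and 1759 without the 4 mixture-like. On the diet they were 3027 with DESeq2, 974 with RLE, 254 without a filter and 77 with limma, and 7, 1, 2 and 1 in the same 4 removals. In the combination they were 2369 without the low-complexity libraries, 846 without all 7 and 2395 without the mixture-like. Against DFMO they were 1440 with DESeq2, 3450 without the low-complexity libraries, 89 without the unmatched and 23 without the mixture-like. Against the diet these removals gave 5424, 1004 and 478. The interaction had 2398 with DESeq2, 9 without the unmatched, 111 without all 7 and 2 without the mixture-like.

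Footprint calls on the diet were 102 with DESeq2, 30 with limma and 57 without mice D5747 and PD5732. Those of the combination against DFMO were 684 with DESeq2, 187 with limma, 248 after thinning, 155 with sex and 1979 without D5747 and PD5732. These mice were removed because they lay between the groups, so the higher count follows in part from that choice. The interaction had 127 with DESeq2 and 828 without both mice.

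Efficiency calls under DFMO were 6162 with limma, 1308 without the low-complexity libraries, 2461 without the unmatched, 735 without all 7 and 2303 without the mixture-like. On the diet they were 1836 with DESeq2, 1066 with RLE, 358 without a filter, 2325 with limma and 245 in 38 libraries, and 119, 276, 54 and 190 in the same removals. In the combination they were 5145 with limma, 658 without the low-complexity libraries, 426 without all 7 and 2026 without the mixture-like. Against DFMO they were 11 with DESeq2, 2 without a filter, 1 with limma, 3 in 38 libraries, 28 without the low-complexity libraries and 1 without D5747 and PD5732. Against the diet they were 265 with DESeq2, 63 without a filter, and 603, 40, 373 and 23 in the removals. The interaction had 837 with DESeq2, 253 with RLE, 439 with limma, 15 in 38 libraries, 456, 2, 163 and 0 in the removals and 98 without D5747 and PD5732.

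Mice as a block need both assays, so that fit also leaves out C5840 and is set against the same 38 libraries without a block. There the block took efficiency calls from 245 to 43 on the diet and from 87 to 44 for the combination against the diet. It left 3 for the combination against DFMO, gave 14 instead of 15 for the interaction, and changed no other count by more than 1.5 times. Of 125 named gene results that passed in the 38 libraries 14 were lost with the block, and of 40 list calls 1, a comparison for lists added after seeing the results.

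Leaving out a mouse gave, for DFMO, the diet, the combination, the combination against DFMO, against the diet and the interaction in turn, 4253 to 6942, 6 to 4511, 4375 to 7082, 426 to 1320, 1447 to 4046 and 341 to 3231 in RNA. In footprints it gave 1547 to 2419, 0 to 17, 3197 to 4455, 123 to 1152, 2573 to 4180 and 24 to 210. In efficiency it gave 2665 to 4999, 36 to 3073, 2049 to 4799, 0 to 3, 41 to 289 and 2 to 1667.

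Without the unmatched libraries the A-ending codon score could not be called under DFMO in RNA (-0.730, adjusted p = 0.0816) or efficiency (0.914), since 3 mice against 4 controls allow no exact p under 0.0571, so this removal does not test those calls. In the combination, with 4 mice a side, RNA (-0.536) and efficiency (0.634) both reached the smallest exact p possible, 0.0286, and did not pass once adjusted (adjusted p = 0.0714). Efficiency on the diet (0.630) and footprints under DFMO (0.272) kept all their mice and lost their calls through the adjustment alone (adjusted p = 0.0714), as footprints did without the low-complexity libraries, where RNA and efficiency had 1 control and no exact test. Leaving out a mouse also raises the smallest p possible. Without single mice the score ran from -0.750 to -0.629, -0.678 to -0.468 and -0.636 to -0.532 in RNA, 0.228 to 0.328, 0.0552 to 0.170 and 0.0822 to 0.175 in footprints and 0.867 to 1.05, 0.524 to 0.737 and 0.602 to 0.789 in efficiency.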

Other observations

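Pancreatic enzyme genes differed widely between libraries, and they were looked at only after seeing their values. The 6 pancreatic members of the fixed list of kidney, liver, pancreas and muscle markers averaged 3.46 ± 1.94 log2 CPM in control footprints, 0.596 ± 0.837 under DFMO, 0.945 ± 0.886 on the diet and 5.43 ± 1.53 in the combination (SD, n = 5). Controls (1.71 to 6.41) overlapped the combination (4.04 to 7.2). An exact test of the combination against the diet alone, made on these genes after their values were seen, gave p = 0.00794, the smallest possible with 5 mice a side, and is no independent evidence. With group means taken out, the other members followed Cpa1 across 20 footprint libraries at r = 0.801 to 0.932. Their summed footprints reached 1090 CPM in combination mouse PD5732 and 1050 CPM in PD5825, and 840 CPM in control C5840. RNA of the same genes summed to 40.9 to 390 CPM in the combination and 2.5 to 6.71 CPM in controls. These controls are not the same set, since C5840 had no RNA library. Control C5696, at 195 CPM in footprints, had 3.74 CPM in its RNA, which was of low complexity. Abdominal tumors lie close to the pancreas, so adjacent tissue in the dissected piece could give this pattern as well as any expression in tumor cells, and the counts cannot separate them. The whole list kept its interaction call with an estimated correlation (adjusted p = 0.015).

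The neuropeptide gene Vip also appeared in footprints. It had no footprint in any of 5 controls and averaged 26.7 CPM under DFMO and 8.34 CPM in the combination, at least 138-fold and at least 43-fold with 3 counts allowed over the control group. The glial genes Fabp7 and Erbb3 rose in footprints under DFMO (4.22 and 2.04), in the same libraries in which neuronal genes rose.

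A hypothesis written down before its test was that mitosis genes were lower in the combination than under DFMO alone because they are rich in codons ending in A. The median A-ending share of the list was 0.254, at percentile 83.5 of all genes, so codon content could by itself have set it apart. The 58 mitosis genes with a scored coding sequence had a median footprint change of -0.366, while 10000 random lists matched for A-ending share had a median of -0.0405 and a lowest value of -0.206. The real list thus stood at percentile 0 of the matched lists, which speaks against A-ending codons as the cause. Matched lists are drawn gene by gene and do not carry the correlation among mitosis genes, so this percentile overstates the evidence that the list moved beyond chance. The list call itself was lost with an estimated correlation (adjusted p = 0.597).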
